A study of Bacillus subtilis subsp. subtilis NCIB 3610 = ATCC 6051 = DSM 10 with 3 samples.

How the data were processed

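RNA from wild type and from slrAx2 was hybridised together on custom Agilent arrays, 1 array per biological replicate and 3 arrays in all. Per the labels, cells were stopped with cold methanol, RNA was extracted with hot phenol and treated with DNase, and 6 to 10 µg were labelled with Cy3 and Cy5 through amino allyl coupling. The labels call the replicates biological and give the dye of each genotype, which set the direction of every ratio. Each array held both genotypes, so the array pairs them and no other block was fitted. The 3 arrays differed in slide and scan, so no batch held more than 1 array.

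The scanner tables hold the intensity of each spot in both channels as deposited, not normalized, per the file headers, together with the scanner software's own log10 ratio of red over green. That software was Feature Extraction 10.7.3.1 per the file headers and 8.5.1.1 per the submitters' processing notes. A deposited series table gives log2 ratios of wild type over slrAx2 per array and the authors' median fold over arrays, which was not used for any test. The deposited series matrix holds log2 ratios of green over red, not turned for dye. Apart from that turn, it differed from the series table by at most 5.0e-06. The scale and direction of both were found by setting them against the scanner ratios (r across genes of 0.991, -0.983 and 0.993 on replicates 1, 2 and 3 for the series table, and of -0.991, -0.983 and -0.993 for the series matrix). The medians of the series table were 0.01, 0.15 and 0.02 and those of the series matrix -0.01, 0.15 and -0.02, so neither was centred on 0 at the gene level, and the authors' normalization is not given in the sources used here. Another 6 columns of the series table with values per sample were not used. The genome build behind the probes is not given in the sources used here, and no coordinates were used.

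Each array carried 14868 probes other than controls, 3 per feature, and 536 control spots. Gene names and locus tags were taken from the deposited series table, which names 4292 genes. The remaining 664 features have no row there and were kept apart. The scanner tables used here give median and no mean spot signals, so medians replaced the mean signals of the planned design. Signals were background corrected with normexp (offset 50), which pulls the ratios of dim spots towards 0, and normalized by loess within each array with control spots at weight 0. A probe was kept when it was well above background in either channel on at least 2 arrays, which left 12664 probes of 4280 genes. Probes of a gene were averaged. In 13 genes the probes disagreed in sign with a gap of at least 2-fold, among them comK and spoIIIAE of the lists and 0 of the named genes. No probe was saturated.

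Spots with an outlier flag of the scanner software (7.62%, 3.23% and 15.8% of probes on replicates 1, 2 and 3) were kept. The planned design had no such exclusion, and leaving these spots out removes most of the bright fla/che genes, from 32 to 3 measured. This was settled after that loss was seen, and the values with flagged spots left out are given with the alternatives.

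The mean log2 ratio per gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Tables were read with jsonlite 2.0.0, and plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. The lists of genes, 20 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 20 lists. A list needed at least 3 measured members. The estimated correlation ran from -0.15 for the autolysins to 0.97 for PBSX, with 0.93 for fla/che, 0.89 for the ribosomal proteins and 0.80 for the matrix operons. For lists far above the preset of 0.01, camera's p-values at the preset are too small. Counts of members were made over all genes tested, where 0 passed in every list, and adjusted over the list alone. In the text, rose and fell refer to members that passed the latter. Members were matched by current or older symbols, and sdpC was not matched under those names.

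The genes named in the text follow a rule fixed before the data were examined. It takes slrA, slrR, sinR, sinI, epsA, tapA, tasA, bslA, flgB, fliG, sigD, hag, motA, lytC and lytF. It adds the 8 largest rises and 8 largest falls among genes past the threshold in the same direction on all arrays, of which there were 0. From each list it takes the 2 passing members with the largest change or, with none passed over all genes, the 1 member with the largest change. Other genes are said to have been chosen after their values were seen, apart from members listed to account for a count of a list.

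The procedure was tested on simulated data with the real signals and spreads of the 4280 genes, 200 of them changed by known folds. It called 0%, 20%, 40% and 48% of genes changed 2-fold, 4-fold, 8-fold and 16-fold, with the right direction in 92% of the first and 100% of the others, and called 4 unchanged genes. With a variance trend and robust moderation the shares were 4%, 42%, 72% and 82%, with 3 unchanged genes called. A simulated 4-fold change was recovered with a median of 1.46 on the log2 scale. Errors were drawn independently for each gene, and the changed genes were picked at random. The fla/che genes had an estimated correlation of 0.93 and a median SD over arrays of 1.16, against 0.46 over all genes. The shares called therefore need not hold for the operons described below.

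Alternatives covered the background correction, the normalization within and between arrays, the scanner's own ratios, the filter on dim probes, the summary over probes, a dye term, the variance model, a minimum change of 1.2-fold (treat), both deposited tables, each replicate left out, and the set test. The exclusion of saturated spots would have removed 0 probes and was not run. For slide and scan no within-batch value could be formed with 1 array in each.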

Results

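Transcripts of the undomesticated Bacillus subtilis strain NCIB 3610 were compared with those of a derivative carrying 2 copies of slrA, written slrAx2 here. The slrA gene encodes a small protein that antagonises the biofilm repressor SinR. Cultures were harvested from LB broth at an optical density at 600 nm of 1.0 to 1.1. Each of the 3 biological replicates was 1 array that held both genotypes in different dyes, so every array gave a direct ratio of slrAx2 over wild type. The slrAx2 RNA was in Cy3 on replicates 1 and 3 and in Cy5 on replicate 2. The median probe signal of the slrAx2 channel was 210, 128 and 584.75 intensity units on replicates 1, 2 and 3, over background medians of 17, 44 and 20. For wild type the signals were 194, 428.5 and 388, over 45, 18.5 and 43.5. The probes well above background numbered 80.6%, 81.0% and 93.9% in slrAx2 and 78.6%, 95.6% and 91.6% in wild type. All ratios below are log2 of slrAx2 over wild type, as the mean ± SD of the 3 arrays (n = 3). The number of arrays limits their precision.

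The first question was whether the extra copy raised the slrA transcript, and what happened to the genes of the SinR and SlrR switch. The slrA transcript (BSU38229) was higher in slrAx2 on every array, at 2.32 ± 0.75 (SD, n = 3), which is 4.99-fold, with single values of 2.23, 1.62 and 3.12. The slrR gene (BSU34380), which encodes the partner of SinR in repressing motility genes, stood at 1.64 ± 0.69, or 3.12-fold higher (1.26 to 2.60 over the alternatives). Both rose when the p-values were adjusted over the list alone, 2 of the 10 regulators measured. Without replicate 1, without replicate 3 or with scaling between arrays 0 of the 10 passed, and with a dye term 1 did. The genes of the repressor and its anti-repressor were lower on each array by less than 2-fold and did not pass, with sinR at -0.41 ± 0.12 and sinI at -0.37 ± 0.16. Over all 4280 genes tested, limma's adjusted p was 0.128 for slrA, 0.235 for slrR, 0.619 for sinR and 0.693 for sinI. The list had a median of -0.01 and a mean of 0.30, which differ in sign, and it did not pass the set test (camera upwards, adjusted p = 0.622, or 0.672 with an estimated correlation).

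Transcripts of the biofilm matrix operons were several-fold higher in slrAx2. All 18 measured genes of the eps operon, for the exopolysaccharide, and of the tapA operon, for the amyloid fibre, rose when adjusted over the list alone, with a median of 2.91 (7.51-fold). The largest change was that of epsK (BSU34265) at 3.47 ± 0.95, or 11.1-fold. The first gene of the operon, epsA (BSU34370), stood at 2.25 ± 0.79, the fibre subunit gene tasA (BSU24620) at 2.64 ± 0.43, or 6.24-fold, and tapA (BSU24640, named yqxM in the table) at 1.31 ± 0.25 (1.17 to 2.38 over the alternatives). The list's medians were 3.25, 1.98 and 3.13 on replicates 1, 2 and 3. It passed camera with the preset correlation (adjusted p = 9.6e-26) and did not with an estimated correlation (adjusted p = 0.322). No member passed over all genes, where the adjusted p was 0.149 for epsA, 0.0884 for tasA, 0.130 for tapA and 0.101 for epsK.

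Transcripts of the flagellar and chemotaxis operon were lower, at the median by more than 10-fold. All 32 genes of the fla/che operon, which encodes the flagellar basal body, the chemotaxis proteins and the sigma factor SigD, fell when adjusted over the list alone, with a median of -4.42 (21.4-fold lower). The largest change in the operon was that of fliI (BSU16240), the gene of the export ATPase, at -5.16 ± 1.27, or 35.8-fold lower. The promoter-proximal flgB (BSU16180) stood at -3.62 ± 1.39, the rotor gene fliG (BSU16220) at -4.49 ± 1.35 and sigD (BSU16470), near the end of the operon, at -3.12 ± 0.61, or 8.70-fold lower. The list's medians were -4.32, -3.36 and -5.64 on the 3 arrays. Camera gave an adjusted p of 3.3e-43 with the preset correlation and an adjusted p = 0.322 with an estimated correlation. Over all genes the adjusted p was 0.149 for flgB, 0.103 for fliG, 0.0884 for sigD and 0.0884 for fliI.

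**Figure D1:**
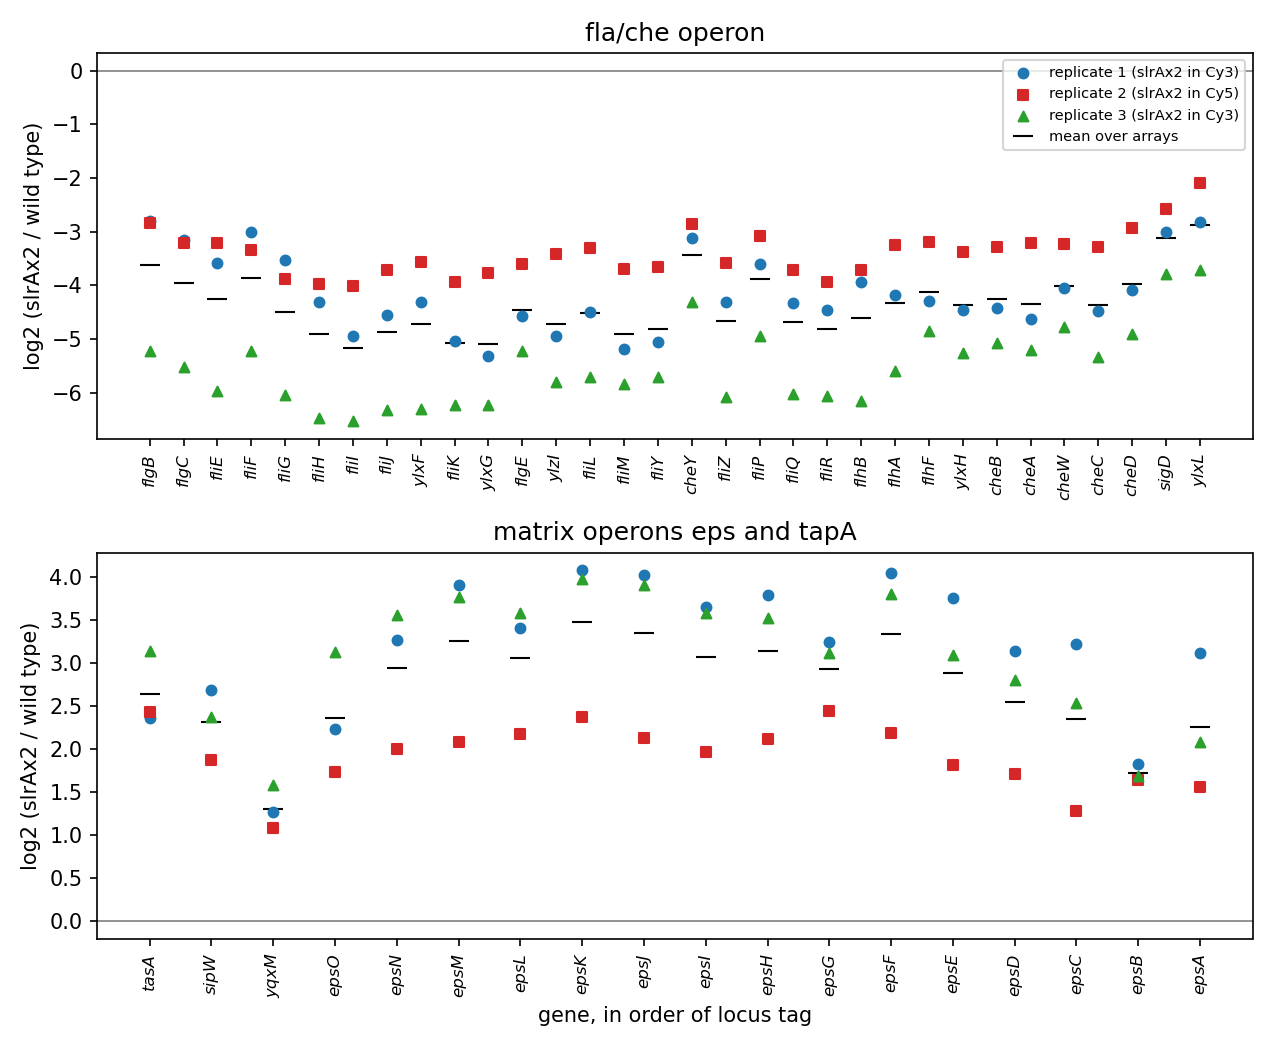
Log2 ratio of slrAx2 over wild type for each gene of the fla/che operon (top) and of the eps and tapA operons (bottom), in order of locus tag, with 1 point per replicate array and a dash for the mean. All 32 fla/che genes lie below 0 and all 18 matrix genes above 0 on each of the 3 arrays.

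Genes that SigD transcribes outside that operon were lower as well. Of 40 measured, 34 fell when adjusted over the list alone and 6 did not pass, with a median of -2.76 (6.78-fold lower). The flagellin gene hag (BSU35360) showed the largest fall, -6.75 ± 1.15, or 107.3-fold lower, with single values of -7.00, -5.49 and -7.74. The stator gene motA (BSU13690) stood at -3.74 ± 1.06, or 13.4-fold lower (-5.15 to -3.43 over the alternatives), with its slrAx2 signal well above background on 2 of the 3 arrays. The 6 that did not pass were named after their values were seen: csrA at -0.27 ± 0.43, yjcP at -1.39 ± 1.10, tlpB at -0.54 ± 0.21, degR at -0.47 ± 0.16, yoaH at -0.58 ± 0.31 and yvzB at -0.18 ± 0.17.

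Camera gave this list an adjusted p of 1.5e-39, and 0.322 as the adjusted p with an estimated correlation. Over all genes the adjusted p was 0.0884 for hag and 0.101 for motA. Among the 6 measured autolysins of cell separation, the 3 under SigD fell when adjusted over the list alone, lytC (BSU35620) at -3.15 ± 1.11 (-4.27 to -2.57 over the alternatives), lytF (BSU09370) at -2.90 ± 0.83 (-4.16 to -2.59) and lytD at -1.99 ± 0.50. The other members, lytE at -0.45 ± 0.09, cwlS at -0.30 ± 1.08 and cwlO at 0.28 ± 0.13, did not pass. The list median was -1.22, with an adjusted p of 0.00117 in camera, 0.322 as the adjusted p with an estimated correlation and an adjusted p of 0.00619 in fry. Over all genes the adjusted p was 0.130 for lytC and 0.104 for lytF.

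Genes for the secreted polymer poly-gamma-glutamate were higher and those for the lipopeptide surfactin lower. Of the 4 measured members of the first list, 3 rose when adjusted over the list alone, with a list median of 3.47 (11.1-fold). The largest was pgsC (BSU35890) at 4.04 ± 1.01, or 16.4-fold. The member that did not pass, pgsA at 0.45 ± 0.40, is a phospholipid synthesis gene at another locus (BSU16920), matched through a shared name. The list's counts, median and p-values include it. The polymer operon's own gene is named capA in the table (BSU35880), and stood at 3.68 ± 1.05, a value looked up after the list was scored. All 5 surfactin genes fell when adjusted over the list alone, with a median of -2.38 (5.22-fold lower). Among them srfAB (BSU03490) stood at -2.58 ± 0.48, and the competence gene comS, which lies inside srfAB, at -2.38 ± 0.44. Camera gave adjusted p-values of 7.3e-06 and 4.5e-09 for these lists, and adjusted p-values of 0.347 and 0.322 with an estimated correlation. Over all genes the adjusted p was 0.0905 for pgsC and 0.0884 for srfAB.

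The PBSX prophage and ribosomal protein genes had high list medians that differed between arrays. The 31 PBSX genes, which encode a defective phage particle and its lysis proteins, had medians of 0.50, 5.70 and 4.05 on replicates 1, 2 and 3. The member with the largest change, xepA (BSU12780), stood at 3.64 ± 2.83, with its wild-type signal well above background on 2 of the 3 arrays, and 0 of 31 passed when adjusted over the list alone. That count depended on the processing, as 21 to 29 of the PBSX genes passed under 10 of the alternatives. The 53 ribosomal protein genes had medians of -0.22, 2.62 and 0.27, with rpsJ (BSU01150) at 2.23 ± 3.11 (0.44 to 3.24 over the alternatives) and 0 of 53 passing, against 33 with a dye term. A dye term fits replicate 2, the only array of its orientation, exactly. The residual spread then comes from replicates 1 and 3 alone, so a gap to replicate 2 no longer counts as error. Both lists passed camera with the preset correlation (adjusted p = 1.0e-15 and 2.9e-05) and neither did with an estimated correlation (adjusted p = 0.420 and 0.613). Without replicate 2 the ribosomal median was 0.04 and the call ended (adjusted p = 0.590).

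Other lists that camera called with the preset correlation had no member that passed when adjusted over the list alone in the reported fit. A few passed under some alternatives. With a dye term these were 4 of the 5 lactate, 2 of the 9 ATP synthase and 1 of the 11 exoprotease genes. In either of the deposited tables they were 2 of the 5 bacillibactin and 1 of the 11 cannibalism genes. Leaving out spots with an outlier flag gave 3 of the 7 pyrimidine genes then measured, and leaving out replicate 1 or replicate 2 gave 1 exoprotease gene. The 10 pyrimidine synthesis genes had a median of 0.82, with pyrP (BSU15480) at 1.30 ± 0.64, and the 9 ATP synthase genes one of 0.68, with atpC (BSU36800) at 1.06 ± 0.78 (0.62 to 1.35 over the alternatives). Without replicate 1 these medians were 0.53 and 0.44. The 5 genes for the siderophore bacillibactin had a median of 1.56, from 3.30 on replicate 1 to 0.59 on replicate 2 and 0.67 without replicate 1, with dhbE (BSU31980) at 1.65 ± 1.45 (0.82 to 2.17 over the alternatives). The 14 purine synthesis genes had a median of 0.37, with purN (BSU06510) at 0.63 ± 1.09 (0.05 to 1.13 over the alternatives), and without replicate 2 it was -0.08 (adjusted p = 0.591). The purine call also ended with median centring, with scaling between arrays and with the scanner's log ratios (adjusted p = 0.0793, 0.0554 and 0.0600). The 11 other biofilm surface and exoprotease genes had a median of 0.66. In that list the subtilisin gene aprE (BSU10300) stood at 2.08 ± 1.31 and the hydrophobin gene bslA (BSU31080, named yuaB in the table) at 1.86 ± 1.13, with an adjusted p of 0.383 for bslA over all genes.

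Lower medians were found for the 5 lactate utilization genes, -1.25 with lutP (BSU34190, named yvfH in the table) at -1.76 ± 1.81 (-2.71 to -0.91 over the alternatives). The lactate medians were -0.05, -2.16 and -1.04 on replicates 1, 2 and 3, and -0.59 without replicate 2. The 21 general stress genes under SigB had a median of -0.42 with hpf (BSU35310, named yvyD in the table) at -1.56 ± 1.31, and the 11 measured cannibalism toxin genes one of -0.29 with sdpA (BSU33750) at -1.35 ± 0.84, its slrAx2 signal being well above background on 2 of the 3 arrays. The adjusted p-values of these 8 lists were 9.5e-05 for pyrimidine synthesis, 9.5e-05 for ATP synthase, 0.00117 for bacillibactin, 0.0271 for purine synthesis, 0.0279 for the exoprotease list, 0.00342 for lactate utilization, 0.000161 for SigB and 0.00588 for cannibalism. With an estimated correlation the adjusted p was 0.322, 0.347, 0.420, 0.613, 0.613, 0.439, 0.554 and 0.420 in the same order. The SigB medians were -1.39, -0.46 and 0.12 on replicates 1, 2 and 3. With a replicate left out the SigB median ran from -0.78 without replicate 3 to -0.11 without replicate 1 (adjusted p = 0.445 in the latter case). The cannibalism median ran from -0.47 without replicate 1 to -0.14 without replicate 2 (adjusted p = 0.140 in the latter case), and without replicate 3 the exoprotease median was -0.02 (adjusted p = 0.515). The exoprotease call also ended without replicate 1, with median centring and with a dye term (adjusted p = 0.0664, 0.0551 and 0.114).

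The lists for competence, early sporulation and arginine synthesis did not pass camera, and 0 of their members passed when adjusted over the list alone. The 21 competence genes had a median of -0.06 (adjusted p = 0.142), with nucA (BSU03430) at -1.04 ± 0.34. With either deposited table the competence list passed, at a median of -0.30 (adjusted p = 0.0393), while the reported values gave it an adjusted p of 0.420 with an estimated correlation. The 19 early sporulation genes had a median of 0.01 and a mean of -0.08 (camera downwards, adjusted p = 0.911), with spoVG (BSU00490) at -0.88 ± 0.82 (-1.33 to -0.53 over the alternatives). The 9 arginine genes had a median of 0.05 (adjusted p = 0.707), with argC (BSU11190) at 0.15 ± 0.04.

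**Figure D2:**
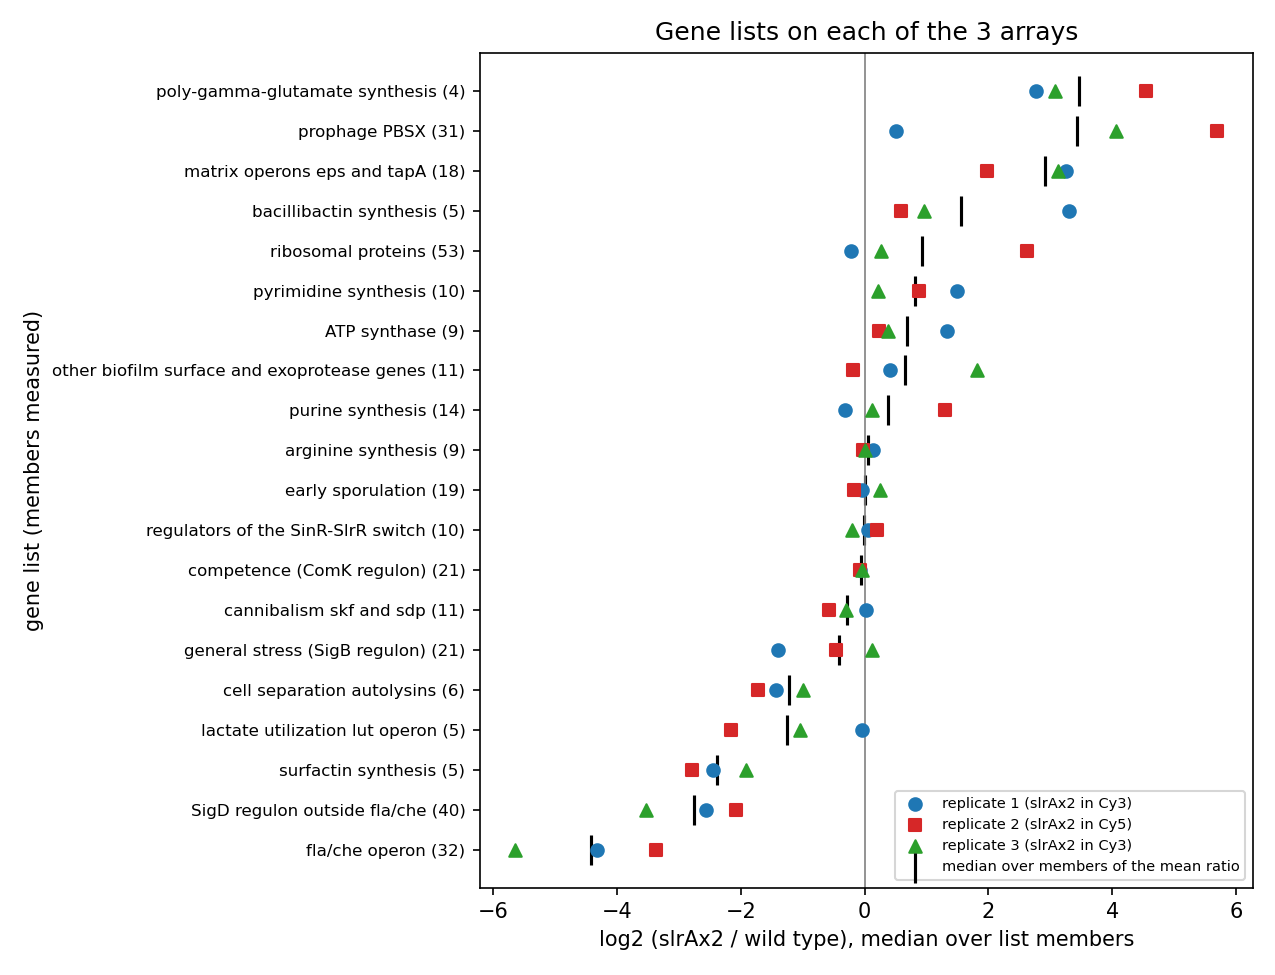
Median log2 ratio of slrAx2 over wild type over the measured members of each of the 20 lists (number in brackets), with 1 symbol per replicate array and a bar for the median of the members' mean ratios. The fla/che medians are -4.32, -3.36 and -5.64 and the matrix medians 3.25, 1.98 and 3.13, whereas PBSX ranges from 0.50 to 5.70.

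Across the whole genome the large changes of motility and matrix genes stood in a noisy background. In limma, 0 of 4280 genes passed an adjusted p of 0.05, the smallest adjusted p being 0.0884. Of the 4280 genes 385 had an unadjusted p under 0.05, where 6.10% of the unchanged genes did so in the simulation. With a variance trend and robust moderation on the same ratios 98 genes passed, 71 lower and 27 higher in slrAx2. These included all 32 fla/che genes, 29 other SigD genes and 16 matrix genes, and in this fit slrA had an adjusted p of 0.0429. At least 2-fold changes in the same direction on all 3 arrays were shown by 101 genes lower and 43 higher in slrAx2, against 3.54 and 2.32 if the arrays were independent. Over all genes, 1293 (30.2%) had the same sign on the 3 arrays, against 25% by chance, and the median SD over arrays was 0.46. The correlation of ratios across genes, which are not independent replicates, was 0.163 between replicates 1 and 2, 0.471 between 1 and 3 and 0.536 between 2 and 3. With the motility and matrix lists left out these were -0.01, 0.22 and 0.45. The count of genes past the threshold depended on the processing, as 7 of the 17 alternatives called 53 to 99 genes. These 7 overlap, since the deposited series table and series matrix hold the same ratios apart from the turn for dye.

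**Figure D3:**
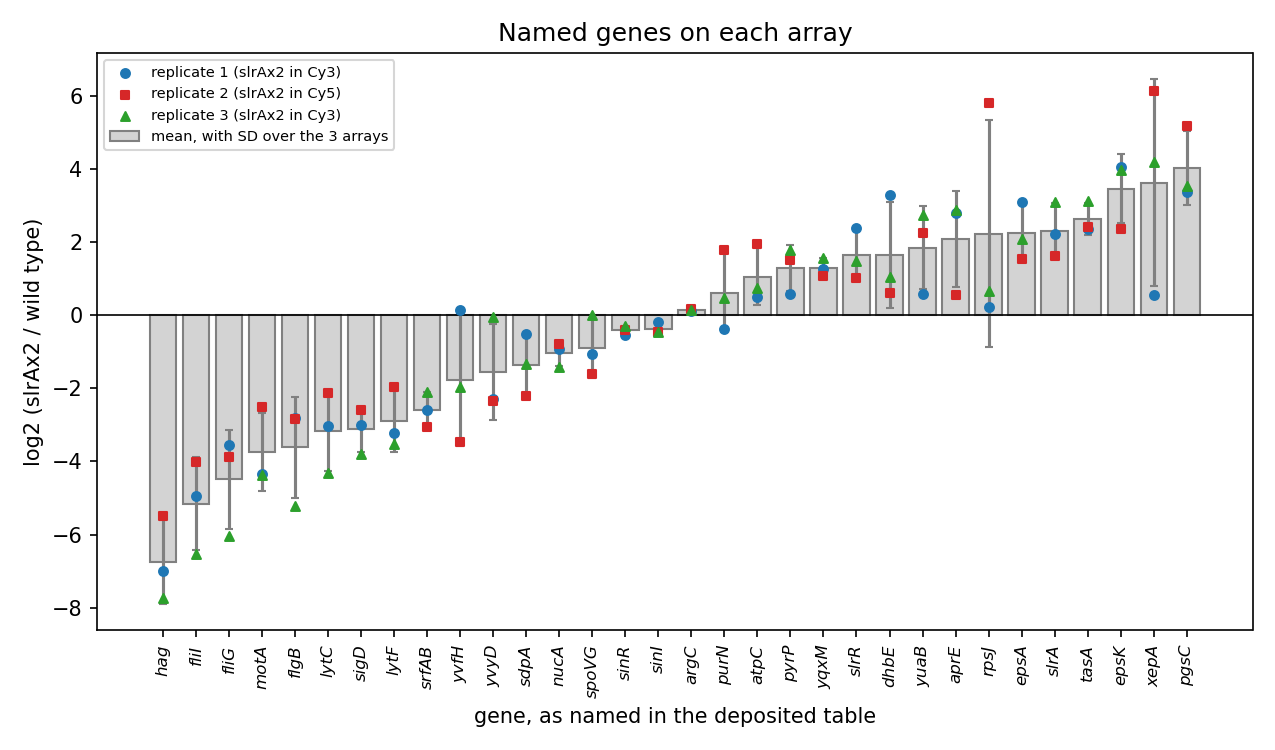
Log2 ratio of slrAx2 over wild type for the genes named by the fixed rule, as bars for the mean with error bars for the SD over 3 arrays and 1 symbol per replicate. The lowest bar is hag at -6.75 and the highest pgsC at 4.04, while xepA and rpsJ have the widest spread between arrays.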

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

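The explanations weighed below were tested after the patterns were seen, although the prediction for the LexA-controlled genes was written before their values were looked at.

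Features of the array without a row in the deposited gene table were tested in one fit with all other features, 4788 in all, and 0 of the 508 tested passed the adjusted p of 0.05. Those at least 2-fold higher in slrAx2 than in wild type on all 3 arrays were picked out. They are M9_1080_- at 1.88 ± 0.19 (log2, SD, n = 3), M9_1081_- at 1.98 ± 0.28, LB_1961_- at 2.26 ± 0.85, LB_1960_- at 2.22 ± 0.97 and EG:EBBACT00000003916 at 1.81 ± 0.87. The limma adjusted p was 0.0930 for each of the first pair and 0.176, 0.229 and 0.277 for the others. In the other direction, EG:EBBACT00000001895 was at least 2-fold lower on all 3 arrays, at -2.28 ± 0.87 (adjusted p = 0.182). What these features are is not stated in the sources used here.

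The lower flagellar and higher matrix transcripts in slrAx2 were set against 3 technical explanations. A dye bias would turn the sign on replicate 2, the array with slrAx2 in Cy5, but the fla/che median there was -3.36 (SD over members 0.43). The loess normalization would have to create the difference, but with arrays only centred on their medians the fla/che median was -4.51 (SD 0.54). The matrix median on replicate 2 was 1.98 with loess and 1.24 with median centring, where replicates 1 and 3 gave 3.48 and 3.27. With median centring 0 matrix genes passed over all genes, against 5 to 16 under the other alternatives that called any gene. A mislabelled array would show slrA lower in the channel labelled slrAx2, but its lowest log2 ratio was 1.62 (SD over arrays 0.75). These values argue against each as the whole cause of the lower fla/che transcripts. The dye and loess tests did not cover the matrix genes, although their medians kept their sign. An effect of the extra slrA copy is the hypothesis left open. A difference in growth state between the cultures, which may also move these genes, was not tested.

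The PBSX transcripts were higher in slrAx2 on replicates 2 and 3, with list medians of 5.70 and 4.05, and at 0.50 on replicate 1. Replicates 1 and 3 share their dye orientation, yet differed by a median of 3.58 over members (SD 0.92), which argues against a dye bias. With median centring in place of loess the lower of the medians on replicates 2 and 3 was 3.86 (SD 1.01), which argues against loess. A DNA damage response on the same arrays would raise the LexA-controlled genes outside the prophage by at least 0.5, but the lower of their medians on those replicates was 0.070 over 16 genes (SD 0.30). Prophage activity that varies between cultures may account for the pattern, and was not tested.

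With 3 arrays there are 4 ways to turn their signs, so no share under 0.05 can be reached. The real orientation gave 385 genes with an unadjusted p under 0.05 and the highest other 182, and 16 lists past camera's threshold against 10, so that 1 of the 4 turns, the real one, reached each real value.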

How the results depend on the processing

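The alternative with outlier-flagged spots left out was chosen after seeing the data, and all other alternatives before. Over the 17 alternatives slrA and the named genes kept the direction of their ratios wherever they were measured, though sizes moved (purN from 0.046 to 1.13, rpsJ from 0.44 to 3.24), and slrA ranged from 1.92 to 2.67, with an adjusted p from 0.0429 to 0.622. The signs of the fla/che, SigD and matrix medians held throughout, over -4.98 to -3.89, -3.63 to -2.43 and 2.62 to 3.29. The number of genes past the threshold was 0 in the reported fit and under 10 alternatives, flagged spots left out included (3979 genes tested, 332 with an unadjusted p under 0.05). It was 81 with a normexp offset of 0, 68 with median centring in place of loess, 99 with the scanner's own log ratios, 53 with both channels above background on all arrays, 98 with a variance trend and robust moderation, and 96 with either deposited table. Of the 109 genes called by any of these 7, 42 were called by all, 40 of them lower in slrAx2. Of the 42, 39 belonged to the fla/che or SigD lists and 0 to the matrix list. The deposited tables hold the same ratios apart from the turn for dye, so these 7 are not independent of each other. The slrA transcript then passed with the scanner's log ratios (2.67, adjusted p = 0.0493) and with trend and robust moderation (2.32, adjusted p = 0.0429). Without replicate 1, 2 or 3 the count was 0 in each case, with a smallest adjusted p of 0.311, 0.0561 and 0.414. All 32 fla/che genes passed over the list alone under every alternative except that with flagged spots left out, where 3 were measured and all 3 passed. The 2 regulators past their own list, slrA and slrR, were 0 with scaling between arrays, without replicate 1 and without replicate 3, and 1 with the dye term. The PBSX genes past their own list, 0 in the reported fit, were 21 to 29, all higher in slrAx2, under 10 alternatives, the dye term and replicate 1 left out among them. With the dye term, which fits replicate 2 exactly and takes the residual spread from replicates 1 and 3 alone, 33 of the 53 ribosomal protein genes passed theirs. Of the 20 lists 16 passed camera with the preset correlation, 0 with an estimated correlation and 1, the autolysins, with fry, where the adjusted p was 0.0752 for each of the fla/che (median -4.42), SigD (-2.76) and matrix (2.91) lists. Medians near 0 changed sign without a call in either state. For early sporulation it was -0.018 with an offset of 0, -0.000116 with both channels above background, -0.0055 with the median over probes, -0.015 with the dye term, -0.080 with either deposited table, -0.0039 with flagged spots left out, and from -0.076 to 0.101 with a replicate left out. Arginine synthesis gave -0.076 with either deposited table and competence 0.027 with median centring. The regulators gave 0.0073 with scaling between arrays, 0.0054 with the median over probes and from -0.075 to 0.092 with a replicate left out. Medians with a call in the reported fit changed sign for the exoprotease list without replicate 3 (-0.016, from there to 1.07 with a replicate left out) and for purine synthesis without replicate 2 (-0.080, from there to 0.741), and both calls ended. The cause of these shifts was not tested. The weak slrAx2 channel of replicate 2 (median signal 128 over a background of 44) limits what dim genes can show.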

Other observations

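The genes and groups in this part were chosen after their values were seen, and so were the tests, although both predictions on the SigW genes were written before the remaining members were looked at.

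Outside the fixed lists, 17 genes were at least 2-fold higher and 33 at least 2-fold lower in slrAx2 on all 3 arrays. These counts include capA of the polymer operon. They also include ykzL and yviE, whose locus tags lie between those of listed PBSX genes and listed SigD genes. Among the higher ones were pksJ (2.13 ± 0.11, log2, SD, n = 3) and pksL (1.63 ± 0.43) of the polyketide cluster for bacillaene. The cluster's 15 measured pks genes had medians of 1.14, 0.01 and 1.78 on the 3 arrays. The endoglucanase gene eglS stood at 2.46 ± 0.71, the expansin gene exlX at 2.53 ± 1.18 and the DNA repair gene ung at 1.51 ± 0.17. The neighbouring yvkA, yvkB and yvkC, each picked as 1 of the 17 higher genes, had a median of 1.64. Among the lower ones were yolA at -3.20 ± 0.57, iseA, which encodes an inhibitor of autolysins, at -2.56 ± 0.48, and the alpha-amylase gene amyE at -2.69 ± 1.22. The contact-dependent toxin gene wapA stood at -2.62 ± 1.01, and with 5 genes named from the same region (yxxG, yxiF, yxzC, yxzG and yxiM) it gave a median of -1.71. All of them are among the 33 lower genes, so this median follows from that pick. No other genes of the region were included. The limma adjusted p over all genes was 0.0884 for pksJ, yolA and iseA, 0.109 for eglS, 0.101 for ung, 0.161 for wapA, 0.223 for amyE, 0.235 for exlX and 0.128 for pksL. The gene pgdS, whose product degrades poly-gamma-glutamate and which SigD transcribes, stood at -2.96 ± 0.65, while the synthesis gene pgsB stood at 3.78 ± 0.85. Both had an adjusted p of 0.0884.

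Several of the lower genes (pspA, ydjG, ydjH, ydjI, yceC, spo0M, yqfA, yqfB, yuaG, yuaI, yvlA and yvlB) are known targets of SigW, the sigma factor of the cell envelope stress response. A hypothesis formed on these 12, with a median of -1.74, is that the SigW regulon may be lower as a whole in slrAx2. The 44 other measured members of a SigW list had a median of -0.74 (SD 0.50), which is below the -0.5 that the hypothesis required. Any operon partners of the 12 among them were not set apart. Over all genes 30.2% had the same sign on all 3 arrays, in either direction, and of these 44 members 27 were lower and 0 higher. Their medians were -1.58, -0.35 and -0.19 on replicates 1, 2 and 3, and 0 of 44 passed when adjusted over their list alone, so most of the shift came from replicate 1. A dye bias would put replicate 2 above 0, and its median of -0.35 (SD 0.79) lay within the members' spread of 0, so this prediction was not decided. The 27 genes lower on all 3 arrays were counted by their sign on each array, replicate 2 included, so their sign there is no test of a dye bias. Replicates 1 and 3 share their dye orientation, so dye does not account for the gap between their medians. A part played by dye in the 44 members stays open.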
